A study of Mus musculus with 7 samples.

How the data were processed

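RNA polymerase II (RNAPII) and acetylated lysine 14 of histone H3 (H3K14ac) were profiled by ChIP-seq in mouse leukaemia cells, with 7 samples in all. The cells were blood progenitors transformed by the MLL-AF9 fusion and resistant to I-BET, an inhibitor of BET bromodomain proteins. Per the labels' protocols, they were kept in 1000 nM I-BET, taken off the drug and transduced with a guide RNA against HBO1 or against the neutral ROSA26 locus. Transduction lasted 24 h and puromycin selection at 5 ug/ml a further 72 h. HBO1 is the lysine acetyltransferase encoded by Kat7, and 2 guides against it were used, called e11 and e12 here. Each guide and antibody had 1 library, so there were no replicates. The ROSA26 input sample had no list of its own and was not analysed here.

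Per the labels' protocols, crosslinked chromatin was sonicated and immunoprecipitated, and libraries were made with a ThruPLEX kit. The submitters' processing notes name bcl2fastq 2, BWA and MACS2 and the builds GRCm38 and mm10, with no further settings. Caller settings, read totals and filters are not given in the sources used here. The deposited peak lists, 1 per library, give each peak's position, a fold enrichment at the summit as a ratio, a -log10 p and a -log10 q, in the layout that MACS2 writes. These values are the authors' own and were used to describe, rank or filter peaks within a list. The list for H3K14ac under e12 held 82 peaks on fly sequences and none on mouse chromosomes. Of these, 5 lay on Uextra, which is not a chromosome arm, and the rest on fly chromosome arms. H3K14ac was therefore compared between ROSA26 and e11 alone.

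Peaks in each list did not overlap each other. A peak of one list was counted as shared when at least 1 bp overlapped a peak of the other list. Genes came from a RefSeq table of GRCm38.p6, the build of the lists, with 21887 protein-coding genes on the main chromosomes. That table gives the start and end of each gene and no strand. The planned promoter window therefore became a window of 1 kb either side of both annotated gene ends, and a peak in it is called a gene-end peak. The planned gene body became the gene interior, more than 1 kb from both ends, in genes of at least 3 kb. A gene-end peak can lie at the 3' end of a gene or belong to a close neighbour, and other genes whose ends lay within 1 kb of the peak were looked up for the named genes. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

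With 1 library per group no test across conditions was possible and no p-value is given. Shares carry Wilson 95% intervals, which cover counting error only. The gene lists, 24 in number, were fixed before the data were examined, as were the rules for named genes. Of 1673 listed names, 1671 were found. Ribosomal protein, proteasome, histone and olfactory receptor lists were taken by symbol prefix. They can therefore hold other genes, such as Rps19bp1 and Psmc3ip. A list's count in a library was set against 10000 random lists of the same size. For members with a ROSA26 peak, the number also called under a guide was set against random lists matched on the ROSA26 -log10 q in 5 strata. For members without one, random lists were matched on whether the ROSA26 library of the other antibody had a gene-end peak. These percentiles describe these libraries only. Genes were named by rule: the 10 with the highest -log10 q under ROSA26 and no peak under the guide, the 10 with the highest under the guide and no peak under ROSA26, and the same for the comparison of all 3 RNAPII lists. Members of the fixed lists of up to 60 genes could also be named. Some genes that meet these rules are not reported here.

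Some alternatives were set before the data were examined. These were a -log10 q of at least 5, an overlap of 50%, a window of 2.5 kb and a summit inside the window. Equal list lengths of 5902 RNAPII and 15069 H3K14ac peaks, and random lists from genes with a nearby peak, were also set then. Where RNAPII and H3K14ac were set side by side, equal length meant 5902 peaks in every list. Leaving out each HBO1 guide, gene list counts at equal list length, a recovery of relative depth, ratios at genes whose counted peaks overlap between libraries, leaving out each member of a list, and the runs of neighbouring peaks for the HoxA cluster were chosen after the data had been seen. In these runs a value expected from strength was the mean overlap, or the median ratio, of the 200 ROSA26 peaks nearest in -log10 q, or in summit over average. For the recovery, the fold was taken as (pileup + 1) / (background + 1) and p as a Poisson probability, and the pileup was solved for at every peak with a -log10 p under 300. Solved pileups lay within 0.002 of a whole number, or within 0.004 of a multiple of one step in the ROSA26 H3K14ac list, whose pileup had been scaled down. The summit pileup was then divided by the background of the whole genome in the same library, giving a summit over average. A library's genome average cannot separate antibody enrichment from a change across the whole genome, and no spike-in scaling was used here.

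Gene-end calling and the recovery were tested on simulated data. Of 200 losses planted among 3000 simulated gene-end peaks, 200 were found with 0 false ones. The simulated guide list was the control list less the planted peaks, at gene ends with no other gene end close by. This result therefore checks the code alone, and says nothing of neighbouring genes, shifted peaks or unequal libraries. In 2000 simulated peaks of each kind, 100.0% of pileups were recovered. Planted depth steps of 0.6 and 0.4 were found as 0.6 and 0.4. These peaks were made with the formula that the recovery inverts, so this result too checks the code alone.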

Results

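The study asked where RNAPII and H3K14ac lie in leukaemia cells after targeting of HBO1, the enzyme that acetylates lysine 14 of histone H3. The cells carried the MLL-AF9 fusion oncogene and were resistant to the BET inhibitor I-BET. A guide against ROSA26 served as the control. RNAPII was mapped under 3 guides, ROSA26, e11 and e12, and H3K14ac is compared under ROSA26 and e11. Each library was a single sample, so no difference below has a replicate check.

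The RNAPII list held 12701 peaks under ROSA26, 37284 under e11 and 5902 under e12. They covered 6.91, 24.6 and 2.96 Mb. The H3K14ac list held 15069 peaks under ROSA26 and 44642 under e11, covering 6.83 and 44.1 Mb. Median peak width was 373 bp under ROSA26 and 642 bp under e11 for H3K14ac, and between 370 and 431 bp for RNAPII. Read totals are not given in the sources used here. Of the RNAPII peaks, 54.8% lay within 1 kb of a gene end under ROSA26, 34.2% under e11 and 64.6% under e12. For H3K14ac these shares were 44.7% under ROSA26 and 29.9% under e11.

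**Figure D1:**
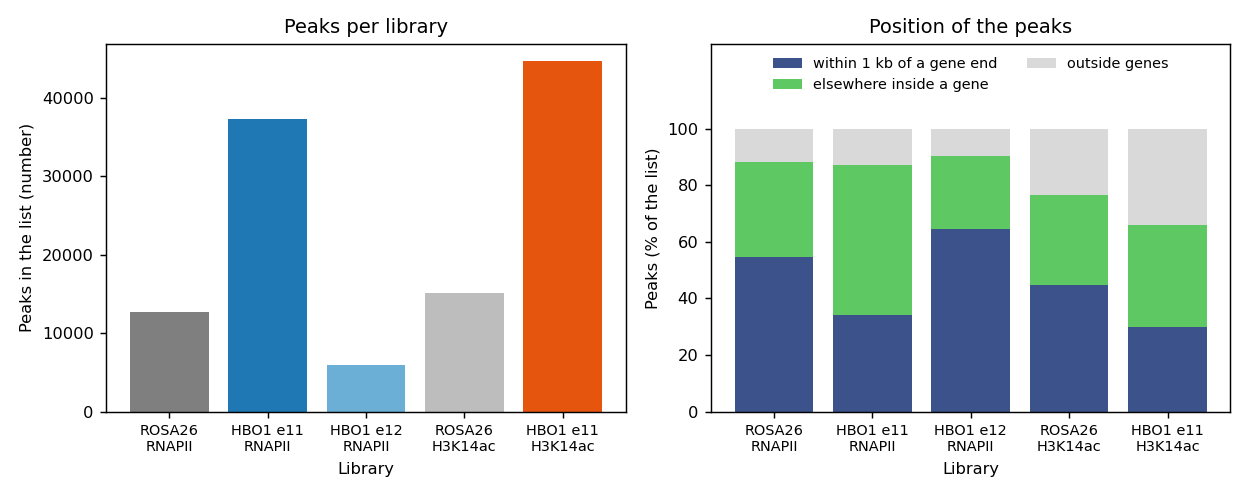
The left panel plots the number of peaks in each of the 5 mouse lists. The right panel plots the percentage of each list within 1 kb of a gene end, elsewhere inside a gene or outside genes, and the e11 lists have the most peaks and the lowest shares at gene ends, 34.2% for RNAPII and 29.9% for H3K14ac.

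Kat7, the gene that encodes HBO1, lies on chromosome 11 from 95271853 to 95310246 (GRCm38). It had an RNAPII gene-end peak under all 3 guides, with a -log10 q of 15.57 under ROSA26, 29.91 under e11 and 20.6 under e12. It also had an H3K14ac peak under ROSA26 and e11. Small edits made by a guide need not remove RNAPII from a gene, so these peaks do not check the labels. Of 10 genes of the HBO1 complex, 6 had an RNAPII gene-end peak under ROSA26, 9 under e11 and 5 under e12. Brpf3, Jade2 and Meaf6, which encode partners of HBO1, had one under all 3 guides.

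The first comparison asks where RNAPII differs between the e12 guide and ROSA26, and the HoxA cluster stood out. These homeobox genes are main targets of the MLL-AF9 fusion. Of 11 HoxA genes, 8 had an RNAPII gene-end peak under ROSA26 and 2, Hoxa10 and Hoxa11, under e12. These counts lay at percentiles 99.92 and 58.6 of random lists from all genes, so the e12 count by itself was not low. Random lists matched on ROSA26 -log10 q kept 5.57 of 8 on average, which put the HoxA count at percentile 0.185. Hoxa7 and Hoxa9 were among the 10 genes with the highest ROSA26 -log10 q and no e12 peak, at 35.69 and 33.96. Across the span of the cluster on chromosome 6, ROSA26 had 29 RNAPII peaks over 28830 bp and e12 had 6 over 3605 bp. Only 3 of the 29 peaks were overlapped under e12, against a mean of 9.99 in runs of 29 neighbouring ROSA26 peaks, at percentile 2.64 of all 12127 runs. HoxA genes are neighbours and share peaks, as Hoxa5 and Hoxa6 do, so they do not count as independent.

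**Figure D2:**
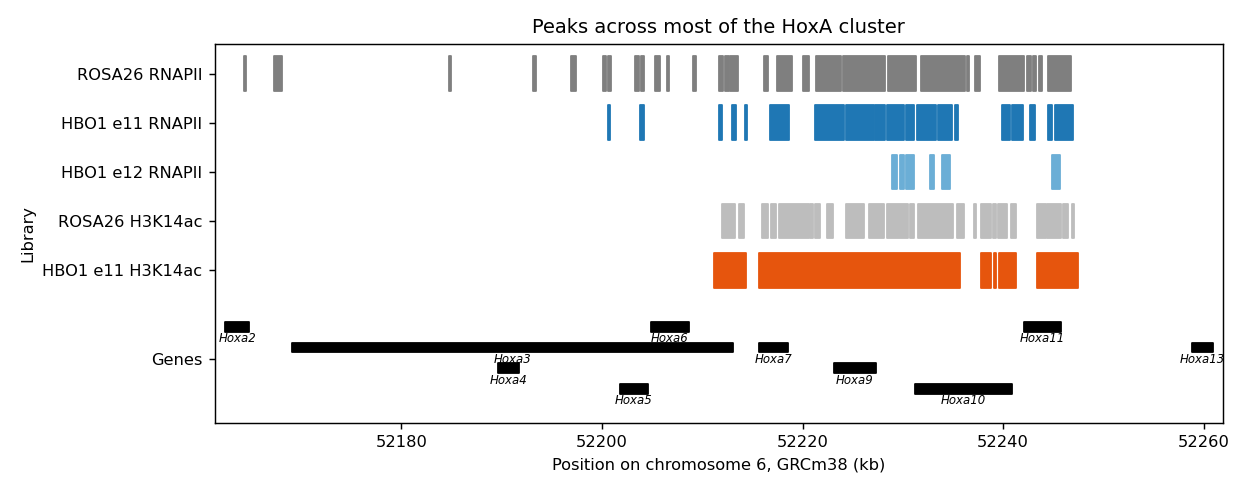
Blocks mark peaks across most of the HoxA cluster on chromosome 6 (position in kb, GRCm38), with a row for each of the 5 libraries and genes in black. Under ROSA26, 29 RNAPII peaks lie in the part drawn, against 19 under e11 and 6 under e12, and 23 H3K14ac peaks under ROSA26 stand against 6 under e11, where neighbouring ones merge.

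Of 18 other targets of MLL fusions, 8 had an RNAPII gene-end peak under ROSA26 and 6 of these kept one under e12, against 5.04 in matched lists (percentile 75.31). Cdk6, Jmjd1c, Lmo2, Myb and Pbx3 had one under both, while Meis1, the usual partner of Hoxa9, had a peak under ROSA26 (-log10 q 11.02) and none under e12. In contrast, all 10 myeloid differentiation genes with a ROSA26 peak also had one under e12, where matched lists gave 6.97, at percentile 99.47. Among these were Cebpa, Cebpb, Cebpd and Cebpe, which encode transcription factors of the granulocyte lineage, and Elane, Prtn3 and Ctsg, which encode granule proteases. The neutrophil genes Ngp and S100a9 had a peak under e12 and none under ROSA26 (2 of 18, percentile 97.09), but so did the stem and progenitor genes Egfl7 and Kit (2 of 12, percentile 97.84). Of 91 genes in the ribosomal protein list, 81 had a peak under ROSA26 and 75 of those also under e12. Myc, whose expression BET proteins sustain, had a peak under all 3 guides.

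Over the whole genome, 34.2% of ROSA26 RNAPII peaks (Wilson 95% interval 33.3 to 35.0) were overlapped under e12. A gene-end peak was present under ROSA26 and not e12 at 2677 genes, and under e12 and not ROSA26 at 318. Several of the highest-ranked genes in the first set shared their ROSA26 peak with a neighbour that had a peak under e12 too. The peak counted for Wdr46 lay at Rps18, that for Zbtb11 at Rpl24, that for Ttyh2 at Rpl38, that for Lta at Tnf, and that for H1f6 at the histone gene H4c3. The peak of Trnau1ap lay at the non-coding gene Snhg12. Ddost had no such neighbour. The e12 list is the shortest, and with equal list lengths 55.0% of ROSA26 peaks were overlapped.

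The second comparison, of e11 with ROSA26, showed RNAPII peaks under e11 at some neutrophil and myeloid genes that had none under ROSA26. Cstdc4, Stfa2 and Stfa2l1, which belong to the stefin cluster of cysteine protease inhibitors on chromosome 16, had e11 peaks with -log10 q of 234.1, 60.2 and 46.64. Of 28 myeloid differentiation genes, 10 had an RNAPII gene-end peak under ROSA26 and 18 under e11. The 8 with an e11 peak and no ROSA26 peak were Camp, Csf1r, Csf3r, Fcgr3, Ly6c2, Ngp, S100a8 and S100a9. Matched lists gave 3.6, which put the count at percentile 99.53. That matching is coarse, since proteasome genes, with 12 of 14 against 7.1, reached percentile 99.97. The count of 18 lay at percentile 99.36 of random lists from all genes but at 38.1 of those from genes with a nearby peak, and at equal list length 8 members had a peak under ROSA26 and 13 under e11.

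HoxA genes kept 7 of 8 RNAPII peaks under e11, with Hoxa2 the exception. In the span of the cluster, e11 had 21 peaks over 21185 bp, and 13 of the 29 ROSA26 peaks were overlapped, against a mean of 25.5 in runs of neighbouring peaks (percentile 0.792). At equal list length, 7 HoxA genes had a gene-end peak under ROSA26, 4 under e11 and 2 under e12. Stem and progenitor genes kept 6 of 8 peaks, against 7.73 in matched lists (percentile 1.43), without Angpt1 and Ikzf2. Of the 12 without a ROSA26 peak, 3 had one under e11, against 2.85 in matched lists. The list of 20 thus had 8 members with a peak under ROSA26 and 9 under e11. At equal list length it had 5 under ROSA26, 5 under e11 and 5 under e12. Of 18 targets of the tumour suppressor p53, 4 had a peak under ROSA26, 12 under e11 and 3 under e12. At equal list length these counts were 4, 7 and 3, and the e11 count fell from percentile 98.58 to 67.47 with random lists from genes with a nearby peak. Members with a peak under e11 alone included Bbc3, Ccng1, Cdkn1a, Sesn1 and Trp53inp1, while the peak counted for Bax spanned the neighbouring ferritin gene Ftl1.

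Of the ROSA26 RNAPII peaks, 87.7% (87.1 to 88.2) were overlapped under e11, while 24.7% (24.2 to 25.1) of the e11 peaks were overlapped under ROSA26. At gene ends, 147 genes had a peak under ROSA26 and not e11, and 2998 the reverse. Among the leading e11 genes, the peak at Vsig4 spanned Mir223, a microRNA gene of myeloid cells, that at Atn1 lay at Grcc10, that at Tmem79 at Smg5, and that at Gtpbp1 at Sun2. Gstp3 and Cdkl4 had no such neighbour, but Cdkl4 had a ROSA26 peak in its interior. Papolg had a peak under ROSA26 and e12 and none under e11.

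Taking both HBO1 guides, Hpgd, which encodes the enzyme that inactivates prostaglandins, led the genes with an RNAPII gene-end peak under ROSA26 and neither guide, with a -log10 q of 24.43, although e11 had a peak in its interior. Aldh7a1 (12.17), Eral1 (12.02), Lrpap1 (10.32) and Tarbp1 (10.31) followed, and then Bicd1, Isoc2a, Thumpd2, Zfp202 and Aplp2. The set held 142 genes over 132 distinct peaks. In the opposite set, with a peak under both guides and not ROSA26, Cstdc4 led, with -log10 q 234.1 under e11 and 56.02 under e12, ahead of Gstp3, Vsig4, Galns and Trappc2l, Dip2b, Gm38529, Tmed3, Gabbr1 and Foxd4. Galns, which had a ROSA26 peak in its interior, and Trappc2l share 1 peak, and the Gm38529 peak lay at Vamp3, which had a peak under all 3 guides. This set held 308 genes over 266 distinct peaks.

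Independent lists would share 66.1 and 59.8 genes. The e12 and e11 lists were nearly nested, since 98.1% (97.7 to 98.4) of e12 peaks were overlapped under e11, and 96.9% of the genes with an e12 peak and no ROSA26 peak also had one under e11. Both comparisons share the ROSA26 library, so part of the excess may come from it. Without e11 the first count was 2677, without e12 the second was 2998, and at equal list length the counts were 599 and 547.

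Marker genes of most other lineages had few RNAPII peaks. Of 13 B lymphoid genes, 0 had a gene-end peak under ROSA26, 1 under e11 and 0 under e12, and of 16 T and NK genes 0, 2 and 0. Of 15 erythroid and megakaryocyte genes, 1, 3 and 2 had one (percentiles 3.335, 5.695 and 40.21 of random lists), so the e12 count was not low. Liver genes gave 0, 2 and 0 of 18, neuronal genes 0, 1 and 0 of 18, and olfactory receptor genes 0, 3 and 0 of 1110. The HoxB, HoxC and HoxD clusters had 0 of 28 under each guide. Housekeeping groups lay high, as for the histone genes, whose near-identical copies make peaks uncertain, with 60, 60 and 58 of 67, and the proteasome, with 26, 38 and 16 of 40. Genes for RNAPII pausing and elongation gave 21, 25 and 10 of 25, replication licensing 18, 22 and 11 of 26, and cell cycle and mitosis 14, 18 and 10 of 20. The MYC and BET list gave 9, 11 and 7 of 13, the MLL, menin and DOT1L complexes 12, 16 and 5 of 18, other acetyltransferases 6, 10 and 4 of 10, and the Wnt pathway 8, 10 and 5 of 20. Interferon-stimulated genes gave 0, 4 and 0 of 18.

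**Figure D3:**
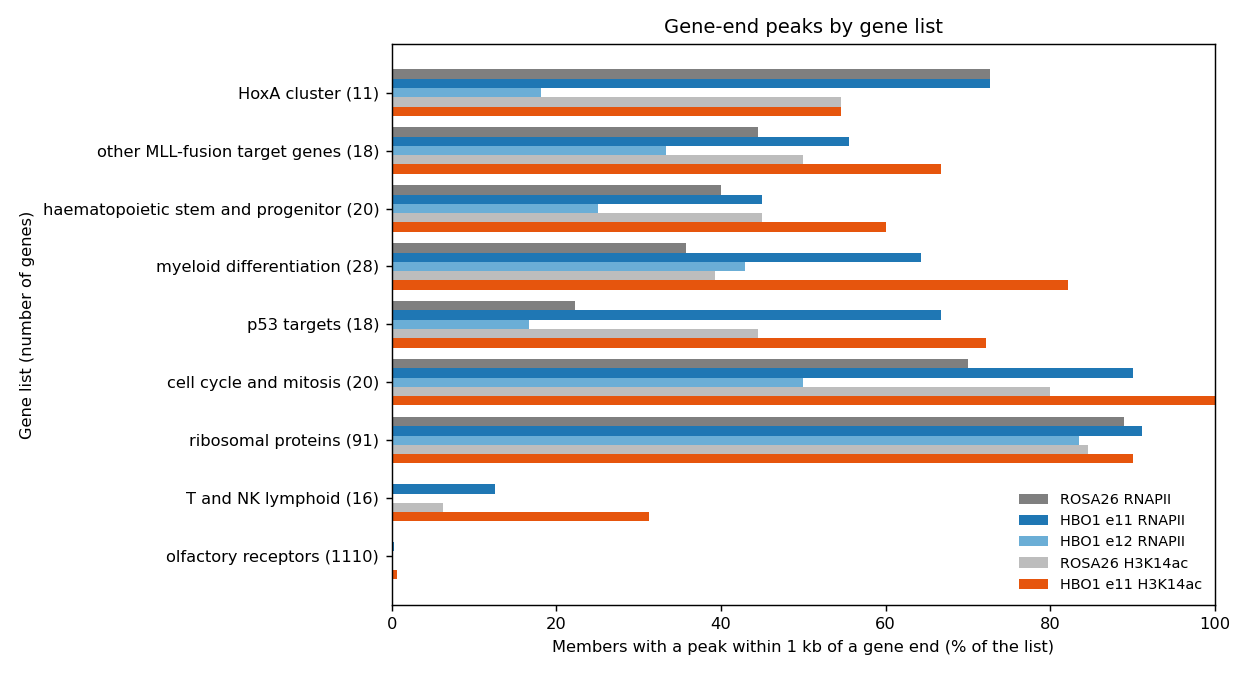
Bars give the percentage of each gene list with a peak within 1 kb of a gene end, per library, with the number of genes in brackets. The HoxA list has 8 of 11 members under ROSA26 and 2 under e12 for RNAPII, and myeloid differentiation genes have 10 of 28 under ROSA26, 18 under e11 and 12 under e12.

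RNAPII inside genes was compared next, since polymerase past the start of a gene is engaged in elongation. This part covers genes of at least 3 kb, which leaves out short genes such as Cebpb and Cebpd. Of such genes with an RNAPII gene-end peak, 28.9% (27.7 to 30.1) also had a peak in the interior under ROSA26, 58.5% (57.5 to 59.6) under e11 and 21.3% (20.0 to 22.8) under e12. On the 2992 genes with a gene-end peak under all 3 guides, the shares were 37.4% (35.7 to 39.2), 74.3% (72.7 to 75.8) and 22.1% (20.7 to 23.7). With all genes of this length that had a gene-end peak in the list concerned, equal list length gave 21.8%, 35.6% and 21.3%. The intervals cover the counting of genes, not differences between libraries in enrichment. A peak with at least 1 bp in the interior counted, so a wide gene-end peak could count as both. With summits required inside, the shares of each list's own genes were 23.4% under ROSA26, 52.1% under e11 and 14.7% under e12.

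For H3K14ac, the mark that HBO1 deposits, nearly every gene marked under ROSA26 was also marked under e11. In the HoxA cluster, Hoxa3, Hoxa7, Hoxa9, Hoxa10 and Hoxa11 had an H3K14ac gene-end peak under both guides, and under e11 Hoxa7, Hoxa9 and Hoxa10 each had an annotated end in a single peak from 52215686 to 52235740. Across the cluster, H3K14ac peaks covered 23469 bp under ROSA26 and 33337 bp under e11. Over the whole list, the length covered under e11 was 6.46 times that under ROSA26. Of the 5 HoxA genes without a ROSA26 H3K14ac peak, 0 had one under e11, against 3.04 in matched lists (percentile 0.07). Myeloid differentiation genes had H3K14ac peaks at 11 of 28 under ROSA26 and 23 under e11. The 12 called under e11 alone, against 4.36 in matched lists (percentile 100.0), included Camp, Itgam, Lyz2, Mmp9, Ngp, S100a8 and S100a9. Here too the matching is coarse, since genes for pausing and elongation (percentile 99.78), the proteasome (99.19) and replication licensing (99.0) lay high as well. The count of 23 lay at percentile 72.3 of random lists from genes with a nearby peak, and at equal list length 11 members had a peak under ROSA26 and 19 under e11. Interferon-stimulated genes went from 2 of 18 under ROSA26 to 11 under e11, with Ifih1, Ifit3 and Bst2 among those called under e11 alone (percentile 99.81). The e11 count lay at percentile 87.31 of random lists, or 61.87 of those from genes with a nearby peak, and at equal list length the counts were 2 and 4.

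At gene ends, 13 genes had an H3K14ac peak under ROSA26 and not e11, among them Fzd4, a Wnt receptor gene, Kynu, Clec9a, Lypd6, Mob3b and Csgalnact1. Their ROSA26 -log10 q was 13.08 at the top-ranked 4931408C20Rik, 6.53 at Fzd4 and 5.39 at Kynu, and lower at the rest, against a list median of 5.99. In the other direction 4431 genes had a peak under e11 alone, led by Cd47, which encodes a signal against phagocytosis, and Unk, Srsf1, Dgka, Anp32a and Wapl. All of these but Dgka had an H3K14ac peak in the interior under ROSA26 and lacked only one near an end. The Dgka peak lay at Pym1, the Gm42166 peak at Lrrc8d and the Crtc2 peak at Dennd4b, each with a ROSA26 peak of its own. Of ROSA26 H3K14ac peaks, 97.6% (97.4 to 97.9) were overlapped under e11, against 23.9% (23.5 to 24.3) of e11 peaks under ROSA26. At equal list length 192 genes had a peak under ROSA26 alone and 2212 under e11 alone, and 193 had one under ROSA26 alone when the summit had to lie in the window.

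RNAPII and H3K14ac were then set side by side at gene ends. Cebpa, Myc and Hoxa9 had both under ROSA26 and under e11, while Hoxa5 and Hoxa6 had RNAPII without H3K14ac under both. Of genes with an RNAPII gene-end peak, 75.5% (74.4 to 76.6) had an H3K14ac one under ROSA26 and 92.7% (92.1 to 93.2) under e11. Over all genes the shares were 27.3% (26.7 to 27.9) and 47.5% (46.8 to 48.1).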

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

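All tests in this part were chosen after the results were seen. The RNAPII list was 2.94 times as long under e11 as under ROSA26 and 0.465 times as long under e12, so the HBO1 guides went opposite ways. This difference between guides was not tested, with 1 library each. The e12 RNAPII library was both shallower and less enriched: its recovered depth was 0.863 times that of ROSA26. At shared peaks its median summit over average was 0.865 times that of ROSA26. For H3K14ac under e12, 82 peaks lay on fly sequences (25 on the arm 2R, 22 on the arm 3R and 5 on Uextra, for example). No mouse list of that library was used here.

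Myeloid genes such as Camp and Csf3r, and p53 targets such as Cdkn1a, had RNAPII peaks in the long e11 list alone, so the length of that list matters for them. More reads in e11 are argued against by the recovered depth of the reads that the caller used. It was 1.03 times that of ROSA26 for RNAPII and 0.358 times for H3K14ac. Read filters are not given, so sequencing depth itself is not known. For H3K14ac, depth over the input was 2.475 under ROSA26 and 0.8865 under e11. The ROSA26 pileup was scaled down to the input for calling, so the depths that acted in calling lay closer together. Higher enrichment over background is in line with the tables: at shared peaks the median summit over average was 1.24 times that of ROSA26 for RNAPII and 5.89 times for H3K14ac. The H3K14ac ratio is uncertain, since a wide e11 peak can stand against several small ROSA26 peaks and e11 peaks with a -log10 p of 300 or more were left out. Whether the enrichment comes from the immunoprecipitation or from the cells stays open, because antibody yield and a change over the whole genome are confounded with the guide.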

How the results depend on the processing

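Leaving out a guide was chosen after the data had been seen; the other settings were not. The nested order of the lists held in each setting run: e12 peaks were overlapped under e11 more often than ROSA26 peaks were. The cause of each shift below was not tested, except that equal length drops the weaker peaks of the longer lists.

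With 50% of a peak to be covered, 83.5% of ROSA26 RNAPII peaks were overlapped under e11 and 23.9% under e12, 96.8% of e12 peaks under e11, and 97.3% of ROSA26 H3K14ac peaks under e11. With a -log10 q of at least 5, the e11 overlap was 87.0%, that of e12 in e11 97.3% and that of H3K14ac 99.1%. At equal list length, the 4 shares were 72.9%, 55.0%, 81.0% and 87.6%.

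Genes with an RNAPII peak under ROSA26 and neither guide numbered 142, and 224 at the stricter threshold, 599 at equal length and 2677 without e11. Those with one under both guides and not ROSA26 numbered 308, and 547 at equal length and 2998 without e12. For H3K14ac, 13 genes under ROSA26 alone became 3 at the stricter threshold, 192 at equal length and 193 by summit, and 4431 under e11 alone became 2212 at equal length.

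The interior share under ROSA26 was 23.7% at the stricter threshold, 21.8% at equal length, 30.8% with the 2.5 kb window and 23.4% by summit. Under e11 it was 41.9%, 35.6% and 52.1% at the stricter threshold, at equal length and by summit, and under e12 18.7%, 24.0% and 14.7% at the stricter threshold, with the wide window and by summit. In each of these settings e11 had the highest share.

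RNAPII genes with H3K14ac were 68.1% under ROSA26 at the stricter threshold, 59.2% at equal length and 76.98% with the wide window. Under e11 they were 94.5%, 68.2% and 93.2%, and 90.0% by summit. Equal length here cut the lists of both antibodies to 5902 peaks. Of 120 gene list percentiles, 66 stayed on the same side of the percentile bounds with random lists from genes with a nearby peak, 51 no longer passed, 3 newly passed and none reversed. Fewer weak peaks pass in a library of low enrichment, so a missing peak does not show an absent protein.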

Other observations

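The tests in this part, and the ratios of summit over average between libraries, were chosen after the results were seen. At stem and progenitor genes with an H3K14ac gene-end peak under ROSA26 and e11, the e11 ratio was low against other genes: the median log2 ratio was 1.83, against 2.52 in random lists matched on ROSA26 enrichment (percentile 0.01). Of the 9 genes, 8 lay below the median of all genes, and the highest median with 1 left out was 2.01 (percentile 0.19). Over the 8 with overlapping counted peaks it was 1.71 (percentile 0.02), and 2.18 without Angpt1 (percentile 4.335). Cd34, a surface marker of progenitors, had 0.27, Ikzf2 0.91, Angpt1 1.07 and Kit 1.24, while Spi1, which encodes a myeloid transcription factor, had 3.28. Genes of the HBO1 complex lay at the other end, with a median of 3.13 over 5 genes (percentile 99.93), as at Brpf3 (3.61) and Meaf6 (3.52). Ribosomal protein genes had 2.24 (percentile 0.0) and histone genes 2.97 (percentile 100.0), the latter with near-identical copies. Hpgd, first among genes with an RNAPII gene-end peak under ROSA26 and neither guide, had an H3K14ac log2 ratio of -0.19.

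For RNAPII, other targets of MLL fusions had a median log2 ratio of -0.142 under e11, against 0.228 in matched lists (percentile 1.77), and of -0.885 under e12, against -0.389 (percentile 0.16). Each rested on single genes, at percentile 12.29 without Jmjd1c and 24.16 without Cdk6. Housekeeping lists reached extreme percentiles with small or large gaps: ribosomal protein genes under e12 had -0.788 against -0.639 (percentile 0.095), and histone genes under e11 0.813 against 0.15 (percentile 100.0). Such percentiles therefore do not by themselves mark a list as special. The implied depth of the input was equal for all 5 mouse lists, at 0.00573 reads per base of genome, as 1 shared input would give.

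HoxA genes had fewer RNAPII peaks under e12 than under ROSA26. Among random lists from all genes, their count lay at percentile 99.92 under ROSA26 and 58.6 under e12. A shorter list, with strength under ROSA26 alone deciding what stays, is argued against by the gene count, at percentile 0.185 of matched lists, and by 3 overlapped peaks against 11.9 expected from ROSA26 strength, at percentile 0.235 of neighbouring runs (2.639 without regard to strength); those 3 peaks had a median log2 ratio of -1.58. A threshold effect in e12 alone is argued against by e11: its median log2 ratio was -0.70 over 7 HoxA genes, against 0.197 in matched lists and lower than in any of 10000 matched lists (percentile 0.0; 0.01 where the counted peaks overlapped), and -0.91 over 13 peaks of the span, with a median of 1.1 below the value expected from ROSA26 strength (percentile 0.01237 among runs). Percentiles among matched lists can be too extreme, since HoxA genes are neighbours, and Hoxa5 and Hoxa6 share a peak. Percentiles among runs can be too extreme as well, since the runs overlap and were not matched on the length they span. The highest summit over average in the span was 63.0 under ROSA26, 30.8 under e11 and 19.4 under e12. A loss of RNAPII at HoxA after HBO1 targeting may account for this, as a hypothesis, which replicate libraries would test. A high value in the single ROSA26 library shared by both comparisons stays open too. At the HoxA genes with an H3K14ac peak under ROSA26 and e11, this mark, which HBO1 deposits, was not lower under e11. Its median log2 ratio there was 2.34 over 6 genes, against 2.5 in matched lists (percentile 18.75). Its highest summit over average in the span was 28.8 under ROSA26 and 121.0 under e11. Less HBO1 would not by itself predict such a rise. The rise cannot be told apart from the higher enrichment of the whole e11 list. Of the 5 HoxA genes without a ROSA26 H3K14ac peak, 0 had one under e11, against 3.04 in matched lists (percentile 0.07). The e11 count of 6 lay at percentile 67.97 of random lists, but at 1.56 of those from genes with a nearby peak.

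Myeloid differentiation genes had more RNAPII peaks under e11 and more H3K14ac. For RNAPII, more calls at active genes in general cannot be told apart from a myeloid effect: the 2 genes called under e12 and not ROSA26, Ngp and S100a9, put the list at percentile 97.09, against 97.84 for stem and progenitor genes, and the median e11 ratio over 10 genes at percentile 96.85, or 99.13 over the 7 with overlapping counted peaks (93.52 without Cebpe). For H3K14ac, a higher enrichment at every gene end alike is argued against by the median log2 ratio of 3.06 over 9 genes, against 2.49 in matched lists (percentile 100.0), and by 2.86 over the 8 with overlapping peaks (percentile 99.91, but 88.47 without Cebpd), with Csf3r at 3.59. Ctsg, at 2.00, and Gfi1, at 2.46, lay below those lists. A ratio was available for 9 of the 11 members with a peak in both lists. Ribosomal protein and histone genes also lay far from matched lists (percentiles 0.0 and 100.0). An uneven H3K14ac ratio is therefore not particular to myeloid genes. A shift towards differentiation under e11 may be a candidate explanation, untested here, which replicate libraries and expression of differentiation markers would test; stem and progenitor genes had a low H3K14ac ratio but an RNAPII ratio near that of matched lists under e11 (0.186 against 0.28, percentile 32.44).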
